A study of Mus musculus with 9 samples.

How the data were processed

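The study profiled poly(A) RNA of thioglycollate-elicited primary peritoneal macrophages from WT, Stat6 S807A (SA) and Stat6 S807E (SE) mice, 3 libraries per genotype. Per the labels, cells were kept in DMEM with 10% fetal bovine serum and collected after brief adherence. RNA was extracted with Trizol and enriched on oligo-dT beads. The deposited table held raw read counts per Ensembl mouse gene for the 9 libraries, as deposited by the authors. The submitters' processing notes name HISAT2 2.1.0, featureCounts (version not given in the sources used here) and the genome build mm10. The annotation release, strand setting and handling of reads that map to several places are not given in the sources used here. Of 55401 gene IDs, 55141 matched the GENCODE M21 annotation by ID and gave symbols and positions, and 260 did not match. All 37 mitochondrial genes had 0 counts in every library, so no share of mitochondrial reads could be used as a sign of RNA quality. Library totals ran from 17286617 to 24618608 counts, at which 3 counts correspond to 0.122 to 0.174 CPM. Such limits cover counting error only.

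Groups followed the genotype labels. All 9 libraries were fitted together in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr on genotype (minimum count 10, minimum total 15), which left 13501 genes, libraries were scaled by TMM, and a robust quasi-likelihood fit with genotype as the only factor gave 6 residual degrees of freedom. The biological coefficient of variation was 6.75%. The contrasts (SA vs WT, SE vs WT, SE vs SA) were tested with the 2-sided quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples.

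Gene lists were written from textbook knowledge. Pathway lists covered IL-4/STAT6 alternative activation, senescence and cell cycle arrest, the SASP, homologous recombination, end joining and damage signalling, p53 targets, G1/S and DNA replication, G2/M and mitosis, type I interferon, interferon gamma and MHC class II, NF-kB, lysosome and autophagy, cholesterol synthesis, LXR targets and lipid storage, glycolysis and hypoxia, nuclear oxidative phosphorylation, NRF2 targets, the unfolded protein response, phagocytosis and the cAMP response. Marker lists covered the macrophage core, resident large peritoneal macrophages, monocytes and small peritoneal macrophages, neutrophils, eosinophils, dendritic cells, B cells, T and NK cells, mast cells and basophils, mesothelial cells and fibroblasts, red cells and platelets, and endothelial cells and adipocytes. Quality lists covered handling stress, ribosomal proteins, replication-dependent histones and mitochondrial transcripts. Of 941 list symbols 934 matched the annotation. The 31 lists with at least 5 tested genes were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, 2-sided, and called at an adjusted p under 0.05 over the 31 lists. Camera compares the genes of a list with all other tested genes. The same test with the correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance, were run beside it. For each list the members passing an adjustment over the list alone were counted too.

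Named genes followed a rule. Stat6, Cdkn1a, Cdkn2a and Il6 were always named. For each contrast the rule added the 6 risen and 6 fallen called genes with the largest change among those with a mean of at least 5 CPM and no overlap between the libraries of the groups, leaving out predicted genes and pseudogenes. It also added the 2 risen and 2 fallen called members of each list with the largest change, the member with the smallest p where a list had none, and the 2 most abundant members of each called marker list. The text gives a part of these. Clec4n, Acta2, Lox and other genes that the closing section names outside the rule were chosen after their values were seen. So were the list members Dcn, Msln and Gata6, given as counts, and Xist, read as a sex-linked gene outside the tested lists. Fold changes are those of the fit, and falls are given as the fold by which the lower group lies below the higher.

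The fit was tested on simulated data drawn from the estimated means and dispersions, with about 50 genes changed at each of 4 folds in the second group of each contrast. At 1.25-fold, 1.5-fold, 2-fold and 3-fold it recovered 44%, 73.5%, 75.5% and 95.9% in SA vs WT (13352 genes), 28%, 75.5%, 89.8% and 93.9% in SE vs WT (13336 genes), and 28%, 64.6%, 77.6% and 95.9% in SE vs SA (13336 genes). False calls made up 7.3%, 5.7% and 11% of the calls, each above the 5% aimed at. The lysosome list, raised 1.15-fold in the same data, was called as risen in each contrast, and 0 of 30 other lists were called. Genes were drawn independently of each other in these data. In the real data the estimated correlation reached 0.413 (G2/M list). The simulation therefore cannot show how often camera falsely calls lists of correlated genes.

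Shared changes of the mutants were described by the Pearson correlation and covariance of their log2 changes from WT, beside 20 simulations of unchanged groups that share the WT libraries. The spread of the covariance was taken as the SD over the values with each library left out in turn. Alternatives were scaling by RLE factors, by upper quartiles or by library totals, no filter on low counts or a mean of at least 5 CPM, DESeq2 1.42.0 or limma-voom in place of edgeR, no robust estimation, only the groups compared in the fit, the replicate number as a block, each library left out in turn, and a 2-fold threshold. The groups, contrasts, tests, lists, rule for named genes and these alternatives were set before the data were examined. Leaving out the pair of libraries at either end of the third principal component was added after the data were seen.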

Results

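Gene expression was measured by poly(A) RNA sequencing in mouse peritoneal macrophages elicited with thioglycollate, an irritant that draws macrophages into the peritoneal cavity. The 9 libraries fell into 3 genotypes with n = 3 each: wild type (WT), Stat6 S807A (SA) and Stat6 S807E (SE). STAT6 is the transcription factor that carries signals from the interleukin-4 and interleukin-13 receptors. Alanine at residue Ser807 cannot carry a phosphate, and glutamate places a negative charge there, a common stand-in for a phosphate. The series title concerns STAT6 phosphorylated at Ser807 and macrophage senescence. The comparisons therefore asked how each mutant differed from WT and how the mutants differed from each other. Library totals were 24618608, 17514211 and 21468846 counts in WT, 22295907, 19141473 and 19357411 in SA, and 20513292, 17286617 and 19771587 in SE. Expression is given as CPM (counts relative to the library total, scaled by TMM) with the SD, n = 3 in each group unless stated.

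Genotype separated the libraries on the leading components of log2 CPM. The first component held 27.9% of the variance and set SA apart from WT and SE, and the second held 18.8% and separated WT from SE. The third held 14.6% and ran across genotypes: WT2 scored -16.24 and SE3 -17.09, whereas WT1 scored 13.29 and SE2 14.85. G2/M genes stood lower in WT2 than in the other WT libraries (list median of -0.17 on the log2 scale) and lower in SE3 than in the other SE libraries (-0.13). Interferon gamma and MHC class II genes stood higher in both (0.12 and 0.11), as did red cell and platelet markers (0.19 and 0.22). Xist, transcribed from the inactive X chromosome of female cells, averaged 935.5 CPM in WT, 960.1 in SA and 805.3 in SE.

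**Figure D1:**
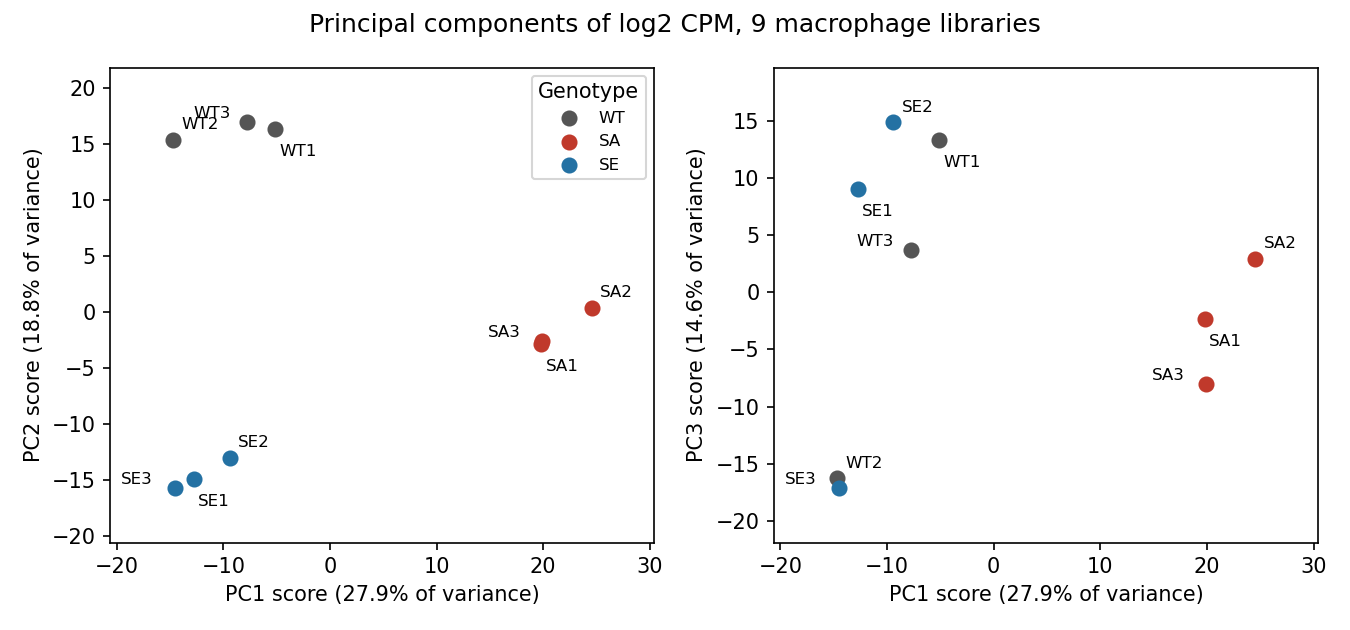
Scores of the 9 libraries on principal components of log2 CPM, with PC1 on both horizontal axes and PC2 (left) or PC3 (right) on the vertical axes. Points are libraries coloured by genotype. The SA libraries lie at 19.82 to 24.53 on PC1, and WT2 and SE3 lie at -16.24 and -17.09 on PC3.

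The edited gene itself was read in every library. Stat6 (ENSMUSG00000002147, mm10 chromosome 10, 127642986 to 127660957) averaged 195 ± 7.53 CPM in WT, 198 ± 2.92 in SA and 296 ± 14.6 in SE. It was 1.51-fold higher in SE than in WT (edgeR adjusted p = 6.27e-06) and 1.49-fold higher in SE than in SA (edgeR adjusted p = 5.15e-06). The difference between SA and WT was 0.02 ± 0.06 on the log2 scale (standard error, edgeR adjusted p = 0.946). Cdkn1a, which encodes the cell cycle inhibitor p21, averaged 223 ± 15.5, 204 ± 5.87 and 219 ± 6.58 CPM in WT, SA and SE, and passed the test in no comparison (edgeR adjusted p = 0.359 for SA vs WT, 0.891 for SE vs WT and 0.324 for SE vs SA). Cdkn2a, which encodes p16, had 0 to 4 counts per library and Il6 had 0 or 1, too few to test at this depth.

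**Figure D2:**
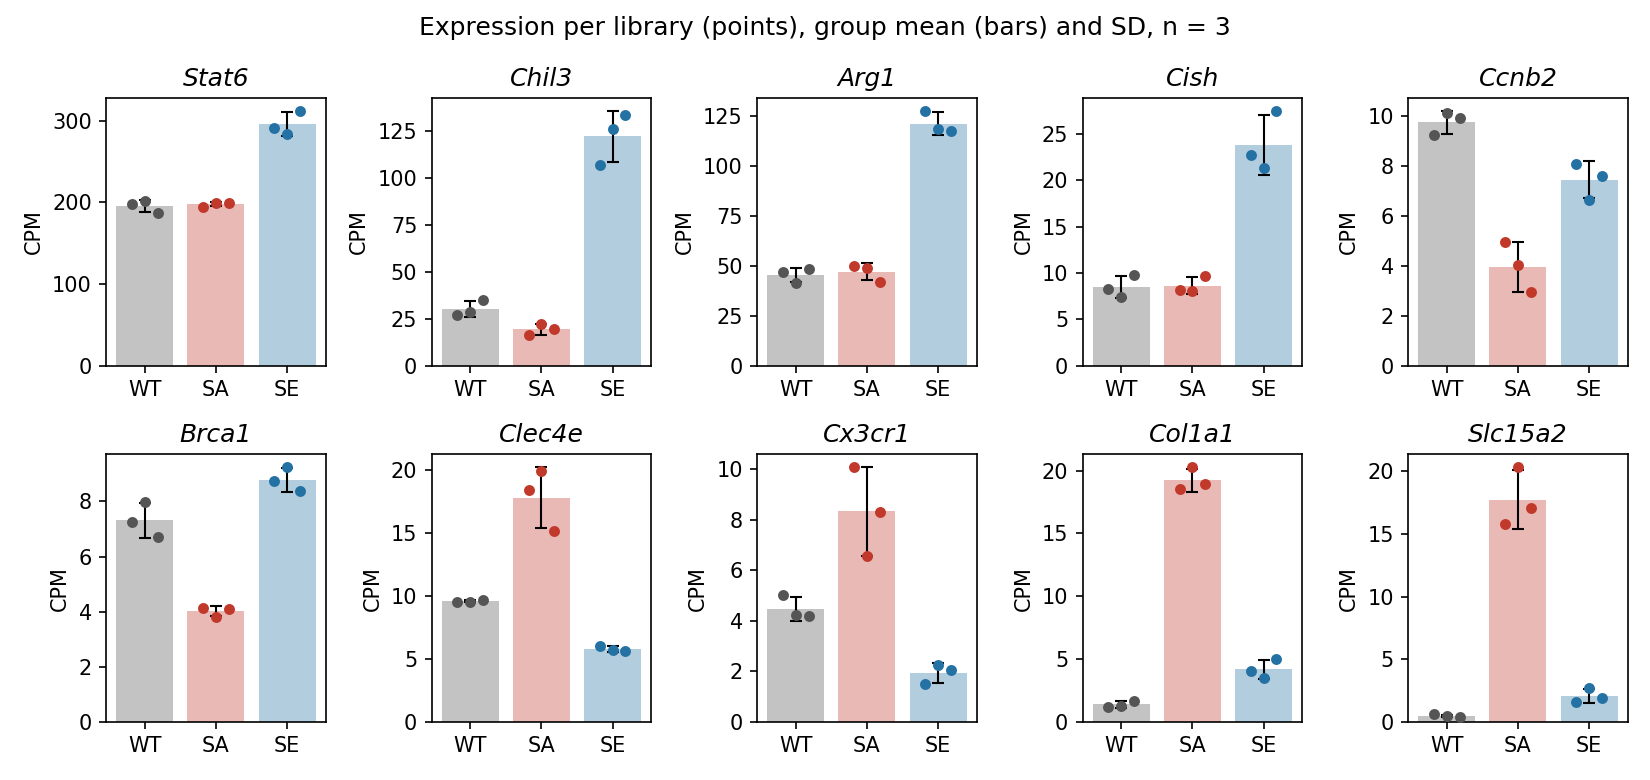
Expression of 10 genes in CPM (vertical axes, starting at 0) by genotype. Bars are group means, error bars are the SD and points are the 3 libraries of each group. Chil3, Arg1 and Cish are highest in SE, Col1a1 and Slc15a2 are highest in SA, Ccnb2 and Brca1 are lowest in SA, and Clec4e and Cx3cr1 are higher in SA and lower in SE than in WT.

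In the SA libraries, collagen genes were among those that rose relative to WT, and 16 of 36 G2/M genes fell. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), averaged 19.2 ± 0.9275 CPM in SA and 1.39 ± 0.253 in WT, a 13.8-fold difference. Col1a2, the other chain of type I collagen, was 9.09-fold higher, Sparc, which binds collagen, was 11.4-fold higher, and Fn1, fibronectin, was 2.73-fold higher. Slc15a2, a transporter of small peptides (ENSMUSG00000022899, chromosome 16), rose from 0.496 ± 0.093 to 17.7 ± 2.35 CPM, 34.8-fold. Ccnb2, cyclin B2 (ENSMUSG00000032218, chromosome 9), fell from 9.75 ± 0.458 to 3.96 ± 1.005 CPM, 2.43-fold lower. Brca1, which acts in homologous recombination, was 1.81-fold lower, at 4.03 ± 0.177 CPM against 7.32 ± 0.642 (edgeR adjusted p = 0.000367). It was the 1 called member of the homologous recombination list of 35, which camera did not call (adjusted p = 0.673). The edgeR adjusted p was 6.91e-11 for both Col1a1 and Slc15a2, 1.16e-07 for Col1a2, 1.7e-09 for Sparc, 1.09e-06 for Fn1 and 4.63e-05 for Ccnb2.

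Among called genes of at least 5 CPM with no overlap between the libraries of the groups, falls in SA also included Cspg4, a chondroitin sulfate proteoglycan (3.52-fold lower), Mamdc2 (2.85-fold), Slco2b1, an organic anion transporter (2.49-fold), Pkp2, a desmosomal protein (2.24-fold), and Adra1a, an adrenergic receptor (2.2-fold). Marcksl1 and Xlr3b rose 2.17-fold and 2.47-fold. Several of these falls were not particular to SA. Mean CPM in SE also lay below WT for Cspg4 (3.2 against 9.09), Mamdc2 (11.3 against 20.6), Slco2b1 (7.83 against 12.7) and Adra1a (5.78 against 10.7). Pkp2 (6.65 in SE against 6.98 in WT) and Xlr3b (3.06 against 2.92) stood near WT in SE, and Marcksl1 lay below it (4.26 against 6.95). Among macrophage genes, Mgl2, a lectin induced by interleukin-4, rose 2.05-fold, and C1qa, a complement component, rose 1.48-fold. Both were also above WT in SE: Mgl2 averaged 13.35, 27.35 and 26.78 CPM in WT, SA and SE, and C1qa 604.7, 892.2 and 724.1 CPM. Cd5l, a protein secreted by tissue macrophages, was 2.02-fold lower. Chil3, a chitinase-like marker of alternative activation, was 1.56-fold lower in SA (edgeR adjusted p = 0.00429), and its call ended when WT2 and SE3 were both left out (edgeR adjusted p = 0.0608). Of 28 IL-4/STAT6 genes 3 rose and 3 fell in SA (7 and 3 adjusted over the list alone), with a median of 0.09, and camera did not call the list (adjusted p = 0.0594, adjusted p = 0.187 with an estimated correlation).

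Of 36 tested G2/M genes, 16 fell and 0 rose in SA (25 fell when adjusted over the list alone), with a median log2 change of -0.47. Hmmr, a spindle-associated protein, was 2.21-fold lower. Camera called the list (adjusted p = 9.87e-19), but the adjusted p = 0.174 with an estimated correlation. Of 8 tested mesothelial and fibroblast markers, 6 rose (7 adjusted over the list alone, camera adjusted p = 6.31e-17), with a median of 3.11. That median rests on Col1a1, Col1a2 and Sparc, above, and on the matrix genes Col3a1 and Bgn. Gsn, the most abundant marker of that list, averaged 852 ± 29 CPM in SA and 773 ± 34.4 in WT (edgeR adjusted p = 0.293). In the same SA libraries Dcn, a fibroblast proteoglycan, had 5 to 10 counts and the mesothelial gene Msln had 0.

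The NF-kB and SASP lists were called higher in SA. In the NF-kB list 9 of 30 members rose and 1 fell (17 and 3 adjusted over the list alone), with a median of 0.24 and a camera adjusted p = 4.06e-10, against an adjusted p = 0.0511 with an estimated correlation. Acod1, which makes itaconate, rose 1.91-fold, and Clec4d, a C-type lectin, was 1.45-fold lower. Clec4d was also low in SE, at 168.9, 116.6 and 108.3 CPM in WT, SA and SE, whereas Acod1 averaged 7.27, 13.8 and 8.14 CPM. In the list of the senescence-associated secretory phenotype (SASP), 9 of 22 members rose and 2 fell (11 and 2 adjusted over the list alone, median 0.35). Its camera adjusted p = 0.000741 became an adjusted p = 0.0511 with an estimated correlation, and the call was also lost among genes of at least 5 CPM, where the median was 0.001. The members of highest fold were of low expression: Cxcl10, a chemokine, rose 2.58-fold to 1.2 ± 0.241 CPM, and Il1b rose 2.3-fold to 1.35 ± 0.168 CPM. The Cxcl10 call ended with DESeq2 and without WT1, WT2, SA2 or SA3 in turn or WT1 and SE2 together (highest edgeR or DESeq2 adjusted p = 0.117). The Il1b call ended with DESeq2, with the replicate block, and without WT1, WT3 or any 1 of the SA libraries or WT1 and SE2 together (highest edgeR or DESeq2 adjusted p = 0.248). Mmp12 and Timp2, a matrix protease and a protease inhibitor of the same list, were 1.45-fold and 1.27-fold lower. In the senescence list 3 members rose, among them Igfbp7 (7.73-fold, to 1.5 ± 0.176 CPM), a secreted protein that fibroblasts also make, in the libraries where matrix genes rose.

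The cholesterol synthesis list was called higher in SA: 12 of 24 rose and 0 fell (19 adjusted over the list alone), with a median of 0.29 and a camera adjusted p = 1.38e-12. Idi1 and Acat2, enzymes of the pathway, rose 1.35-fold and 1.31-fold, and both calls ended without WT2, WT3 or any 1 of the SA libraries. That of Acat2 also ended without WT1, without WT1 and SE2 together, with DESeq2 and with the replicate block (highest edgeR adjusted p = 0.133 for Idi1, highest edgeR or DESeq2 adjusted p = 0.169 for Acat2). Type I interferon genes had a median of 0.20, with 2 of 34 called as risen, Irf7 (1.32-fold) and Ifi44 (1.54-fold), and 14 risen and 1 fallen adjusted over the list alone (camera adjusted p = 2.79e-06, adjusted p = 0.275 with an estimated correlation). The interferon gamma and MHC class II list had 0 of 20 members called by edgeR (0 adjusted over the list alone, 3 higher at an unadjusted p under 0.05) and a median of 0.12 (camera adjusted p = 0.0224, adjusted p = 0.426 with an estimated correlation). Its member with the smallest p, Cd74, averaged 6411 ± 203 CPM in SA and 5711 ± 304 in WT (edgeR adjusted p = 0.168).

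The lysosome, NRF2, LXR and ribosomal protein lists were called lower in SA, each by a small amount. In the lysosome list 4 of 48 members fell (4 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 5.5e-06, adjusted p = 0.174 with an estimated correlation). Ctsd and Ctsl, lysosomal proteases, were 1.36-fold and 1.39-fold lower. Of 28 NRF2 targets 6 fell (11 fell and 1 rose adjusted over the list alone), with a median of -0.16 (camera adjusted p = 6.68e-07, adjusted p = 0.0511 with an estimated correlation), and Gstm1, a glutathione transferase, was 1.49-fold lower. In the LXR and lipid storage list 7 of 23 fell and 1 rose (8 and 5 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0171, adjusted p = 0.275 with an estimated correlation). Fabp4, a fatty acid binding protein, and Pltp, a phospholipid transfer protein, were 1.38-fold and 1.36-fold lower. Of 43 ribosomal protein genes 2 fell, Rpl37 and Rpl38 (2 adjusted over the list alone), and both gene calls ended without WT2, WT3, SA1 or SA2 in turn or WT2 and SE3 together (highest edgeR adjusted p = 0.138 and 0.323). The list had a median of -0.06 (camera adjusted p = 0.00302, adjusted p = 0.52 with an estimated correlation). The LXR and ribosomal list calls each ended without WT2 and without SA2, with medians over all settings of -0.128 to -0.066 and -0.084 to -0.015. The interferon gamma and MHC class II call, above, ended without WT1 (medians of 0.089 to 0.173).

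Across 13501 tested genes, 549 differed between SA and WT by edgeR, 266 higher and 283 lower, of which 78 and 41 changed at least 2-fold (7 and 10 among genes of at least 5 CPM). Scaling by library totals alone gave 304 higher and 229 lower. Camera called 11 of 31 lists, and the cholesterol synthesis and the mesothelial and fibroblast lists kept their calls with an estimated correlation (adjusted p = 0.0414 and 0.017). The count was 297 without WT3 and 308 without SA1. With WT2 and SE3 left out, a choice made after the third component was seen, it was 903, and with the libraries at the other end, WT1 and SE2, left out it was 507.

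SE macrophages were marked by genes of alternative activation, the response of macrophages to interleukin-4. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) averaged 122 ± 13.6 CPM in SE and 30.3 ± 4.27 in WT, 4.04-fold higher. Arg1, arginase 1 (ENSMUSG00000019987, chromosome 10), rose 2.66-fold, from 45.5 ± 3.54 to 121 ± 5.55 CPM. Cish, a feedback inhibitor of cytokine signalling (ENSMUSG00000032578, chromosome 9), rose 2.8-fold, from 8.48 ± 1.2 to 23.8 ± 3.25 CPM, and Retnla, a secreted product of alternatively activated macrophages, rose 2.06-fold to 467 ± 41.4 CPM. The edgeR adjusted p was 3.17e-08 for Chil3, 2.25e-08 for Arg1, 1.45e-06 for Cish and 0.0003 for Retnla, whose call ended with WT2 and SE3 left out (edgeR adjusted p = 0.054). Of 28 tested genes of the IL-4/STAT6 list, 18 rose and 0 fell (20 adjusted over the list alone), with a median log2 change of 0.34. The list held its call with an estimated correlation (camera adjusted p = 1.36e-19 and 0.00126). Stat6 is itself a member of that list.

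Among other genes, Gdf3, a ligand of the TGF-beta family, rose 2.68-fold in SE, and H2-Q6 and H2-Q7, nonclassical class I genes, rose 2.96-fold and 3.58-fold. Reads of H2-Q6 and H2-Q7 are hard to assign between such close paralogs. Batf3, a transcription factor, rose 1.58-fold. Among called genes of at least 5 CPM with no overlap between the libraries of the groups, falls included Cspg4 (2.83-fold lower), Slc40a1, the iron exporter ferroportin (2.44-fold), Rab4a, of endosomal recycling (2.03-fold), Camk2b (1.99-fold) and Hpgd, which breaks down prostaglandins (1.92-fold). Cx3cr1, the fractalkine receptor, was 2.33-fold lower, Abca1, a cholesterol exporter, was 1.47-fold lower, and Cd14, a coreceptor for lipopolysaccharide, was 1.41-fold lower.

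The G1/S list was called higher in SE: 8 of 38 G1/S genes rose and 0 fell (17 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.47e-10, adjusted p = 0.326 with an estimated correlation). Uhrf1, which maintains DNA methylation, rose 1.59-fold, and Mcm5, of the replicative helicase, rose 1.49-fold, a call that ended without SE1, SE3 or any 1 of the WT libraries and without either pair at the ends of the third component (highest edgeR adjusted p = 0.281). All 41 nuclear genes of oxidative phosphorylation had positive log2 changes in SE, with a median of 0.14. Of these 5 rose (6 adjusted over the list alone, camera adjusted p = 6.31e-08, adjusted p = 0.324 with an estimated correlation). The list also varied within genotypes, standing 0.13 higher in WT2 than in the other WT libraries and 0.04 higher in SE3 than in the other SE libraries. Random lists matched on length and expression, described below, centred on 0.047 in this comparison. In the unfolded protein response list 5 of 27 rose (8 rose and 1 fell adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.00588, adjusted p = 0.326 with an estimated correlation). Asns, asparagine synthetase, rose 1.41-fold, a call that ended without WT3 or SE1 (highest edgeR adjusted p = 0.181). Its rise was not particular to SE. Asns averaged 8.14, 12.5 and 11.5 CPM in WT, SA and SE, and rose 1.53-fold in SA (edgeR adjusted p = 0.00578). The call in SA ended without SA1 (edgeR adjusted p = 0.0558). Of 20 interferon gamma and MHC class II genes 3 rose (6 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.011, adjusted p = 0.428 with an estimated correlation). Psmb8, of the immunoproteasome, and Cd74, the class II invariant chain, rose 1.23-fold and 1.2-fold. Both calls ended without WT3, and that of Cd74 also without WT1 or SE1, without WT1 and SE2 together and with SA left out of the fit (highest edgeR adjusted p = 0.0679 and 0.0842). In the homologous recombination list 1 of 35 genes rose, Brip1 (1.52-fold), with 0 called adjusted over the list alone (7 higher and 1 lower at an unadjusted p under 0.05 by edgeR), a median of 0.07 and a camera adjusted p = 0.0373 that became an adjusted p = 0.326 with an estimated correlation. The Brip1 call ended without WT1, WT3, SE1 or SE2 in turn or WT1 and SE2 together, with library totals as the scaling and with SA left out of the fit (highest edgeR adjusted p = 0.376).

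Lists called lower in SE than in WT were NF-kB, phagocytosis and NRF2 targets. In the NF-kB list 7 of 30 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0373, adjusted p = 0.428 with an estimated correlation). Clec4e, a C-type lectin that senses mycobacteria, was 1.66-fold lower, Marcksl1 was 1.63-fold lower, and Bcl2a1b, a survival factor, rose 1.42-fold. In the phagocytosis list 6 of 29 fell and 1 rose (7 and 3 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0373, adjusted p = 0.428 with an estimated correlation), and Cd300lf, a receptor for lipids of dying cells, was 1.72-fold lower. Of 28 NRF2 targets 4 fell and 1 rose (8 and 2 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.00805, adjusted p = 0.326 with an estimated correlation), and Me1, malic enzyme, was 1.55-fold lower. Of 8 mesothelial and fibroblast markers 2 rose (5 adjusted over the list alone), Col1a1 (3.02-fold, to 4.18 ± 0.747 CPM) and Sparc (2.15-fold, to 1.53 ± 0.0665 CPM), with a median of 0.85 (camera adjusted p = 0.000123, adjusted p = 0.249 with an estimated correlation). The Sparc call ended without WT1 and SE2 together (edgeR adjusted p = 0.0595). The homologous recombination list call ended without WT2, WT3, SE1 or SE2 in turn (medians of 0.04 to 0.109 over all settings), as did the NF-kB call (-0.111 to -0.021). The phagocytosis call ended without WT2, SE1 or SE2 (-0.1 to -0.069), the NRF2 call without WT2 or SE2 (-0.1 to -0.054), and the interferon gamma and MHC class II call without SE2 (0.106 to 0.195). Genes of at least 5 CPM gave no call for the homologous recombination, NF-kB and phagocytosis lists.

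In total 680 genes differed between SE and WT by edgeR, 317 higher and 363 lower, of which 41 and 27 changed at least 2-fold (13 and 4 among genes of at least 5 CPM). Scaling by library totals alone gave 285 higher and 407 lower. Camera called 10 of 31 lists, and the IL-4/STAT6 list kept its call with an estimated correlation. The count of genes was 1097 without WT2, 292 without WT3, 332 without SE1 and 438 with SA left out of the fit, and the count of lists was 5 without SE2. With WT2 and SE3 left out the count of genes was 1215, and with WT1 and SE2 left out it was 372.

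Set directly against each other, the mutants differed in the IL-4/STAT6, NF-kB, SASP, cholesterol synthesis and fibroblast marker lists, among others. Chil3 was 6.31-fold higher in SE than in SA, Gdf3 3.13-fold, Cish 2.77-fold, Arg1 2.58-fold and Scn3a, a sodium channel subunit, 3.46-fold. Slc15a2 was 8.67-fold lower in SE than in SA, Col1a2 5.03-fold, Col1a1 4.58-fold, Cx3cr1 4.33-fold, Marcksl1 3.53-fold and Clec4e 3.08-fold. For these 11 genes edgeR adjusted p was at most 2.12e-06, the value of Cx3cr1. Il1b, the cytokine interleukin-1 beta, was 6.79-fold lower in SE, at 0.198 ± 0.0803 CPM against 1.35 ± 0.168 (edgeR adjusted p = 0.000285).

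Of the IL-4/STAT6 list, 13 of 28 genes were higher and 1 was lower in SE (17 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 8.28e-11). The lower one was Ccl22, a chemokine, 1.24-fold, a call that ended without SA1 or SA2 (highest edgeR adjusted p = 0.0735). Of the G2/M list, 17 of 36 were higher and 0 lower (24 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.4e-12, adjusted p = 0.188 with an estimated correlation). Hmmr was 2.03-fold higher. In the G1/S list 7 of 38 were higher (8 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 2.64e-05, adjusted p = 0.344 with an estimated correlation), and Pole, a DNA polymerase, was 1.98-fold higher. Of 35 homologous recombination genes, 8 were higher and 3 lower in SE (9 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0678, median 0.03). Brca1 was 2.18-fold higher (edgeR adjusted p = 1.57e-05).

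Lists lower in SE than in SA included NF-kB, SASP, type I interferon, cholesterol synthesis and the mesothelial and fibroblast markers. In the NF-kB list 14 of 30 genes were lower and 1 higher (19 and 1 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 5.45e-11). In the SASP list 7 of 22 were lower and 2 higher (11 and 3 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 4e-04), and the 2 higher ones were Mmp12 (1.38-fold) and Timp2 (1.28-fold). In the type I interferon list 9 of 34 were lower and 1 higher (12 and 2 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.000266, adjusted p = 0.344 with an estimated correlation), and Ifit3, an antiviral gene, was 1.73-fold lower. Of 24 cholesterol synthesis genes 16 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.51e-09). Idi1 was 1.66-fold lower, and the higher one was Dhcr7 (1.26-fold), a call that ended without SA2, SA3, SE1 or SE3 (highest edgeR adjusted p = 0.134). Of 8 mesothelial and fibroblast markers 5 were lower (7 adjusted over the list alone), with a median of -2.07 (camera adjusted p = 3.9e-10), in the same libraries.

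Lists higher in SE than in SA included oxidative phosphorylation, lysosome, unfolded protein response and ribosomal protein genes. Of 41 oxidative phosphorylation genes 13 were higher and 0 lower (18 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 9.9e-09, adjusted p = 0.116 with an estimated correlation). Cyc1, of complex III, was 1.29-fold higher. In the lysosome list 10 of 48 were higher and 1 lower (16 and 2 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.000104, adjusted p = 0.188 with an estimated correlation), and Ctsl was 1.4-fold higher. In the unfolded protein response list 6 of 27 were higher (9 higher and 1 lower adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00394, adjusted p = 0.188 with an estimated correlation), and Ddit3 was 1.34-fold higher. Ddit3 lies within 10 Mb of the edited Stat6 gene. Of 43 ribosomal protein genes 4 were higher (4 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.000104, adjusted p = 0.359 with an estimated correlation). Over all tested genes, log2 change in this comparison had a Spearman correlation of -0.156 with length. Of these lists only oxidative phosphorylation was set against lists matched on length, described below. A length effect on the others was not tested.

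Marker lists of cell identity also moved between the mutants. In the macrophage core list 6 of 20 were lower and 2 higher in SE (6 and 3 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00584, adjusted p = 0.116 with an estimated correlation). Lyz2, the lysozyme gene, averaged 10590 ± 982 CPM in SE and 10070 ± 246 in SA (edgeR adjusted p = 0.723), and Lgals3, galectin-3, was 1.37-fold higher in SE. The macrophage core call ended among genes of at least 5 CPM. Of 10 tested markers of resident large peritoneal macrophages 5 were lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.0305, adjusted p = 0.192 with an estimated correlation). That list call ended with library totals as the scaling, with WT left out of the fit and among genes of at least 5 CPM. Cd93, a surface receptor, was 1.41-fold lower, and Gata6, which specifies resident large macrophages, had 0 or 1 count per library. Of 5 endothelial and adipocyte markers 2 were higher in SE, Pecam1 (1.53-fold) and Fabp4 (1.45-fold), both also made by macrophages, and 4 were higher adjusted over the list alone. The Pecam1 call ended without SA1 or SE1 (highest edgeR adjusted p = 0.0735). That list had a median of 0.35 (camera adjusted p = 0.0121, adjusted p = 0.116 with an estimated correlation).

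SE and SA differed in 1376 genes by edgeR, 644 higher and 732 lower in SE, of which 53 and 120 changed at least 2-fold (16 and 12 among genes of at least 5 CPM). Scaling by library totals alone gave 473 higher and 925 lower. Camera called 15 of 31 lists, and the IL-4/STAT6, SASP, NF-kB, cholesterol synthesis and mesothelial and fibroblast lists kept their calls with an estimated correlation (adjusted p = 0.00773 for the first and 0.0358 for each of the others). The count of genes was 836 without SA1, 781 without SA2, 908 without SA3 and 811 without SE1. With WT2 and SE3 left out it was 1903, and with WT1 and SE2 left out it was 1447.

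**Figure D3:**
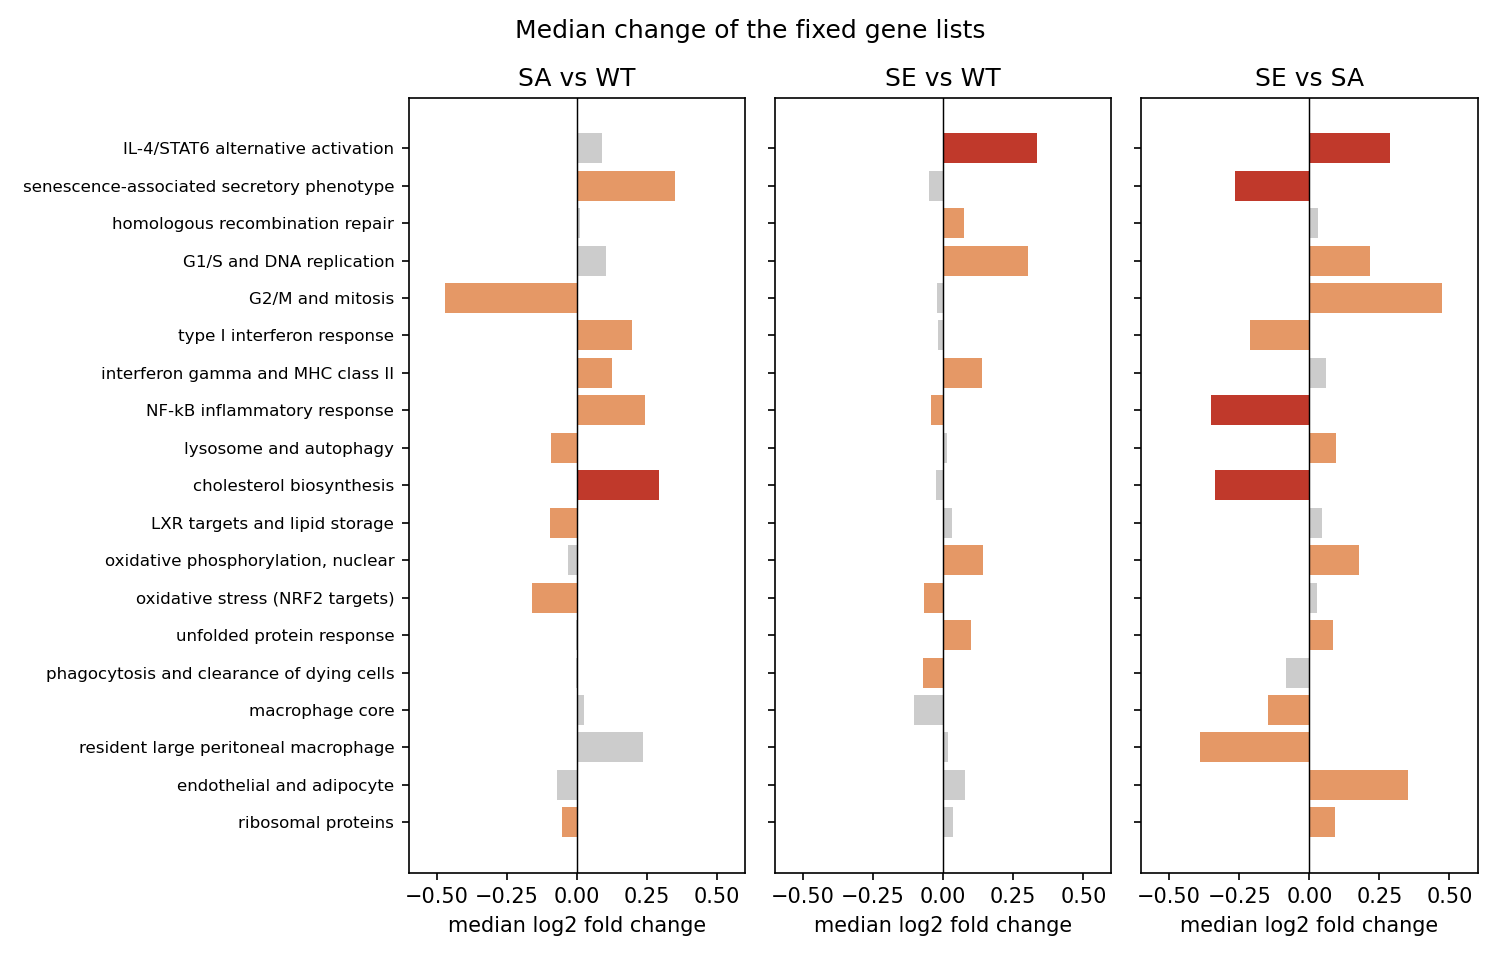
Median log2 fold change (horizontal axes) of the tested members of 19 gene lists, each called in at least 1 comparison, in SA vs WT, SE vs WT and SE vs SA. Dark red bars are lists called by camera that kept the call with an estimated correlation, orange bars are called with the preset correlation only, and grey bars are not called. The mesothelial and fibroblast list, with medians of 3.11, 0.85 and -2.07, lies beyond the axes and is not drawn. The G2/M median is -0.47 in SA vs WT and 0.47 in SE vs SA, and the IL-4/STAT6 median is 0.34 in SE vs WT.

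Some genes were called in both mutants against the same WT libraries. Of the genes called in both comparisons, 36 were higher in both, 70 were lower in both, 16 were higher in SA and lower in SE and 11 were lower in SA and higher in SE. Independent lists of the same sizes would share 6.2, 7.6, 7.2 and 6.6 genes in that order. These are counts without a test of the overlap, since the comparisons share the WT libraries and are not independent. Fn1 was 2.73-fold higher in SA and 1.94-fold in SE, Cspg4 was 3.52-fold and 2.83-fold lower, and Cd5l was 2.02-fold and 1.59-fold lower. Across genes, which are not independent replicates, the log2 changes of the mutants had a Pearson r of 0.459 and a covariance of 0.0478. Both comparisons use the same WT libraries, and simulated unchanged groups sharing them gave r of 0.460 to 0.510 over 20 simulations. Their covariance was 0.0168 to 0.0195, with a mean of 0.0182. The observed r was thus not above that of unchanged groups, but the observed covariance was above the highest simulated value. The simulations drew genes independently, with the same dispersion for a gene in all libraries. Spread particular to the WT libraries, which enters both comparisons, was thus not simulated. The simulated covariance may be too low, so the excess cannot be read as a shared effect of the mutants. The simulations gave 0 genes called in the same direction in both comparisons, against 106 observed. They held at most 3 calls in SA vs WT and 2 in SE vs WT, so their 0 shared calls say little. With the fit run on genes of at least 5 CPM the covariance was 0.0072, and with no filter on low counts it was 0.5914, so its value rests largely on genes of low expression. Within the main fit, the 9553 genes with a mean of at least 5 CPM gave r of 0.275 and a covariance of 0.00825. The simulations were read over all genes only, so whether these genes exceed unchanged groups was not tested.

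Several lists were called by camera in no comparison. In the senescence and cell cycle arrest list of 21 tested genes, 3 rose and 1 fell in SA, 0 rose and 2 fell in SE, and 1 was higher and 6 lower in SE than in SA, with camera adjusted p = 0.57, 0.472 and 0.157. Among the 6, Igfbp7 was 5.53-fold lower in SE, and Gpnmb, a lysosomal glycoprotein, was the higher one (1.38-fold). In the order SA vs WT, SE vs WT and SE vs SA, camera adjusted p was 0.211, 0.472 and 0.821 for end joining and damage signalling, 0.0821, 0.187 and 0.913 for p53 targets, 0.499, 0.215 and 0.614 for glycolysis and hypoxia, and 0.627, 0.225 and 0.157 for the cAMP response. For cell markers camera adjusted p was 0.499, 0.462 and 0.753 for monocytes and small peritoneal macrophages, 0.57, 0.948 and 0.823 for neutrophils, 0.286, 0.613 and 0.712 for eosinophils, 0.0594, 0.533 and 0.0719 for dendritic cells, and 0.622, 0.244 and 0.52 for red cells and platelets. Immediate early and handling stress genes gave camera adjusted p = 0.629, 0.331 and 0.174. B cell, T and NK cell, mast cell and basophil, replication-dependent histone and mitochondrial lists had 3, 3, 2, 4 and 0 testable members and were not tested. Median, mean and test had 1 sign in every called list. They differed in sign in lists not called: homologous recombination, eosinophil, unfolded protein response and handling stress in SA vs WT, LXR, resident large macrophage and neutrophil in SE vs WT, and end joining, p53, interferon gamma and MHC class II, glycolysis, monocyte and eosinophil in SE vs SA.

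Fry, which tests a list without comparing it with other genes, called 12, 11 and 17 lists in SA vs WT, SE vs WT and SE vs SA. Lists called by fry but not by camera in SA vs WT were p53 targets (lower, fry adjusted p = 0.0024), IL-4/STAT6 (higher, 0.00494), macrophage core (higher, 0.00876) and endothelial and adipocyte markers (lower, 0.00773). In SE vs WT they were p53 targets (lower, fry adjusted p = 0.000713), macrophage core (lower, 0.0123) and endothelial and adipocyte markers (higher, 0.0202). In SE vs SA they were senescence and cell cycle arrest (lower, fry adjusted p = 0.0139), phagocytosis (lower, 0.016), the cAMP response (lower, 0.0176), homologous recombination (higher, 0.0176) and monocytes and small peritoneal macrophages (higher, 0.0244). Lists called by camera but not by fry were type I interferon (fry adjusted p = 0.0704), interferon gamma and MHC class II (0.147) and ribosomal proteins (0.213) in SA vs WT, and homologous recombination and interferon gamma and MHC class II (0.0789 each) in SE vs WT. In SE vs SA they were G1/S (fry adjusted p = 0.08), type I interferon and ribosomal proteins (0.0502 each).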

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

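Among the tests given here, those of the matrix genes against mesothelial and fibroblast RNA and that of library scaling were chosen after the results were seen. The tests of flanking DNA, of regrouped libraries and of transcript length were set beforehand.

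The matrix genes that rose in SA, Col1a1, Col1a2, Col3a1, Sparc and Bgn, could come from another cell type in those libraries. RNA from mesothelial cells has little support, since Msln, Upk3b and Krt19 summed to at most 1 count in any SA library. Upk1b, Lrrn4, Krt7, Krt8 and Wt1 of the same list had 0 counts in SA. Aldh1a2, a list member not counted among the fibroblast genes, went the other way. It averaged 1.06 CPM in WT and 2.15 in SA, with every SA library above every WT library. RNA from fibroblasts stays open: 5 of 6 tested fibroblast genes were higher in every SA library than in every WT library, but these 5 are the matrix genes themselves, and the sixth, Pdgfrb, was not (means of 1.47 CPM in WT and 1.87 in SA). Dcn had 5 to 10 and Pdgfra 4 to 6 counts in the SA libraries, against at most 1 in WT, but Lum had at most 1 count. A hypothesis is that a small number of fibroblasts came with the SA macrophages, which counts in sorted cells or single cells would test.

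Genes of oxidative phosphorylation were higher in SE than in SA with a list median of 0.178 (camera adjusted p = 9.9e-09, adjusted p = 0.116 with an estimated correlation). These genes are short (median exonic length 2101 against 4032 bases over all genes), and a length bias between libraries might raise them together. Of 10000 random lists matched on length and expression, 0 reached the median of the list. The matched genes were drawn independently, whereas the genes of the list had an estimated correlation of 0.127, so this count cannot be read as a p-value. Medians of the matched lists centred on 0.07, with 0.015 to 0.114 as their central range, so length may account for part of the difference. Over all tested genes the Spearman correlation of log2 change with length was -0.156 in SE vs SA. It was -0.147 in SE vs WT and 0.034 in SA vs WT. Library scaling does not account for it, since the lowest list median under the other scalings was 0.131, with library totals.

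Both mutants carry an edit in Stat6 on chromosome 10, and DNA beside an edited allele can differ from that of WT mice. Within 10 Mb of Stat6, 4 of 107 tested genes were called in SA vs WT (3.74%, against 4.07% elsewhere, one-sided Fisher exact p = 0.638). In SE vs WT 5 of 107 were called, Stat6 and Ddit3 among them (4.67% against 5.04%, one-sided Fisher exact p = 0.632). In SE vs SA 12 of 107 were called, again with Stat6 and Ddit3 among them (11.2% against 10.2%, one-sided Fisher exact p = 0.409). Of the called genes, 545 of 549 and 675 of 680 lay elsewhere. The window held only 107 of 13501 tested genes, so its local effects could not be the source of most calls against WT whatever the shares. The shares show only that calls against WT were not concentrated near Stat6. Effects of a nearby variant on distant genes, and DNA differences elsewhere in the genome, were not tested.

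Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. In an edgeR fit of the 6 libraries alone, 1 of the 10 splits of SA and WT, the real one, gave as many as 569 genes, and the highest other gave 0. For SE and WT 1 of the 10, the real one, gave as many as 438 and the highest other 0, and for SE and SA 1 of the 10, the real one, gave as many as 1545 and the highest other 1.

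The 27 genes called by edgeR in opposite directions from WT in the mutants were also called in SE vs SA, 16 lower and 11 higher in SE. Opposite calls against the same WT libraries all but bring the latter about, so it adds no separate support. Cx3cr1 had log2 changes of 0.89 in SA and -1.22 in SE, Marcksl1 of 1.12 and -0.70, Thbs1 of 0.82 and -0.70, and Cd14 of 0.32 and -0.50. Chil3 had -0.64 and 2.02, Rnase2a -0.75 and 0.57, and Slc7a2 -0.23 and 0.74. The NF-kB list had a median of -0.351 in SE vs SA.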

How the results depend on the processing

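The alternatives that left out libraries at either end of the third component were chosen after the result was seen. Counts of changed genes moved most with the threshold and the libraries used. With a 2-fold change required as well, genes changed, SA vs WT, were 119, genes changed, SE vs WT, were 68 and genes changed, SE vs SA, were 173, and with SA left out of the fit SE vs WT gave 438. Without 1 library in turn they ran from 297 (without WT3) to 534 (without WT2) in SA vs WT, from 292 (without WT3) to 1097 (without WT2) in SE vs WT, and from 781 (without SA2) to 1220 (without SE2) in SE vs SA. With WT2 and SE3 left out they were 903 in SA vs WT, 1215 in SE vs WT and 1903 in SE vs SA, and with WT1 and SE2 left out 507, 372 and 1447. Lists called with an estimated correlation were 2, 1 and 5. Among genes of at least 5 CPM only 26 lists could be tested, without the mesothelial and fibroblast list, and 9, 6 and 12 were called. Without 1 library in turn the lists called ran from 11 to 15 in SA vs WT, from 5 (without SE2) to 11 in SE vs WT and from 15 to 18 in SE vs SA. The covariance of the mutants' changes was 0.5914 with no filter on low counts, 0.0072 with the fit run on genes of at least 5 CPM, and 0.0496 (without SE2) to 0.0721 (without WT1) without 1 library. With replicate number as a block, 500, 568 and 1189 genes and 13, 10 and 15 lists were called and the covariance was 0.0477, named genes lost 18 calls and gained 0, and lists lost 0 and gained 2. Replicate numbers did not pair the samples: 1 of 9 pairs with the same number had r above 0.1 after group means were removed (-0.195 to 0.105), and 2 of 9 libraries fitted best with their own number, so the unblocked values lead the text. Of the named gene calls, 44 of 62 in SA vs WT, 37 of 66 in SE vs WT and 61 of 95 in SE vs SA held under the alternatives set beforehand for single genes, which did not include the 2-fold threshold, and without each library, and no call turned direction in these settings. The cause of these shifts was not tested.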

Other observations

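The genes given here were chosen after their values were seen. Capn11, a calpain protease gene, averaged 3.751 CPM in WT and 0.03397 and 0.01745 CPM in SA and SE (edgeR adjusted p = 3.79e-07 and 5.08e-07). Hmga2, a chromatin protein gene 10 Mb or less from Stat6, had log2 changes of -0.98 in SA and -0.81 in SE (edgeR adjusted p = 0.000355 and 0.00234). Phgdh, the first enzyme of serine synthesis, averaged 6.515 CPM in WT, 8.956 in SA and 13.1 in SE (edgeR adjusted p = 0.0426 for SA vs WT and 7.02e-05 for SE vs WT), and Mthfd2, a mitochondrial folate enzyme, had log2 changes of 0.51 and 0.59 (edgeR adjusted p = 0.00269 and 0.00084). Psat1, the next enzyme of serine synthesis, rose in SA by 0.49 (edgeR adjusted p = 0.0175), and its value in SE was 0.27 (edgeR adjusted p = 0.21).

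Acta2, smooth muscle actin, had a log2 change of 2.67 in SA vs WT, Lox, which crosslinks collagen, of 2.34, and Ccn2, a matricellular protein, of 3.15 (edgeR adjusted p = 3.89e-06, 1.09e-06 and 7.44e-05). They rose in the SA libraries where the matrix genes rose, and RNA from fibroblasts stays open for them too. Fancd2 and Fanca, of the Fanconi anaemia repair pathway, were higher in SE than in SA by 0.89 and 0.62 on the log2 scale (edgeR adjusted p = 0.00525 and 0.00483). Il1rl1, the receptor of interleukin-33, rose in SA by 0.98 (edgeR adjusted p = 0.00293). Clec4n, dectin-2, was lower in SE than in WT by a log2 change of -0.71 (edgeR adjusted p = 0.0133).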
